A study of Homo sapiens with 28 samples.

How the data were processed

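Total RNA was extracted from human monocyte-derived macrophages with silica columns and made into stranded libraries with a low-input total RNA kit, per the labels' protocols. The libraries came from 7 groups of 4: M0, M1, M1 with TNF, and M1 with TNF combined with a control immunoglobulin, adalimumab, etanercept or certolizumab pegol. The dose of the immunoglobulin is not given in the sources used here. Sample groups and the set codes 1, A, C and D were taken from the labels, and every group holds 1 library of each set.

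The authors deposited 1 table of raw read counts for 36995 gene symbols in the 28 libraries, and its values are whole numbers. Per the submitters' processing notes, reads were handled with cutadapt 1.14, STAR 2.5.0a and featureCounts on the build GRCh38. The annotation release and the strand setting of the counting are not given in the sources used here. Reads of a gene and of a gene overlapping it, or of near-identical copies such as FCGR2A and FCGR2B, FCGR3A and FCGR3B, the MT1 family, the GBP family, HLA genes or HSPA1A and HSPA1B, may therefore be mixed, and values of such genes are uncertain. Of 410 genes that the naming rule chose, 82 overlap another annotated gene, among them CD163, FGL2, GCNT1, ADAMTS4, IFIT1, IFIT2, RSAD2, MPEG1 and NIPAL4. Coordinates are those of the GENCODE annotation of GRCh38, in which 36764 of the symbols were found.

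Library totals were 6107951 to 12985710 counts, with a median of 21672 genes detected per library, and 3944 genes had 0 counts in every library. Counts of PCR-amplified reads are not independent molecules, so the 95% counting intervals and the floor of 3 counts over a group cover counting error only. Genes were filtered with filterByExpr and scaled by TMM in edgeR 4.0.16 (R 4.3.3), and CPM, counts scaled to library size with these factors, were computed for levels. Changes were tested with edgeR's quasi-likelihood test with the set as a block and Benjamini-Hochberg adjustment per comparison, at an adjusted p under 0.05. M1 vs M0 was fitted on all 28 libraries (14546 genes, 18 residual degrees of freedom, biological coefficient of variation 0.197). The other 11 comparisons were fitted together on the 24 stimulated libraries (14284 genes, 15 residual degrees of freedom, coefficient 0.156). Log2 fold changes are given with standard errors, and n is 4 libraries per group except where sets or libraries were left out or split. Every adjusted p of a gene is from edgeR unless another tool is named.

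Whether the set codes pair the libraries was checked before calls were compared. The correlation of deviations from the group means was 0.274 to 0.836 between libraries of the same set over the 21 pairs of groups, and at most 0.258 between different sets. In 168 of 168 cases a library correlated best with the library of its own set. The pairing rests on the set codes of the labels and on this check.

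The 25 gene lists were fixed before the data were examined, as were the comparisons, tests and alternatives. They cover inflammatory cytokines, chemokines, type I interferon targets, NF-kB feedback and TNF response, the TNF ligand and receptor system, MHC class II presentation, alternative (M2) markers, anti-inflammatory regulators, matrix metalloproteinases, TIMPs with ADAM and ADAMTS proteases, Fc gamma receptors and their signalling, complement, inflammasome and pyroptosis, prostaglandin and lipid mediators, glycolysis and hypoxia, cholesterol synthesis and efflux, metallothioneins, wound healing and growth factors, cell cycle, lymphocyte, platelet with erythroid and granulocyte, and monocyte with dendritic cell markers, mitochondrially encoded mRNAs, and stress and heat shock genes. Results of 1 further list, and of some single genes that passed, are not reported here. Each list was tested with camera in limma 3.58.1 at a preset correlation of 0.01 and with an estimated correlation, adjusted over the 25 lists of a comparison. A further planned list test, fry, called 9, 8 and 9 lists for adalimumab, etanercept and certolizumab against IgG, and 0 in TNF vs M1. It is not among the alternatives given for a list. Of 99 calls at the preset correlation, 30 held with the estimated one, and in 64 of the 69 others that p was the highest among the alternatives of the list. List median, mean and test differed in sign in 0 of the 99 list tests that passed and in 37 of the 201 that did not.

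Named genes follow a rule with 3 parts. The first takes up to 8 higher and 8 lower genes per comparison with the largest log2 fold changes among those with an adjusted p under 0.05, an average log2 CPM of at least 1 and the same direction in all 4 sets, leaving out clone-style, antisense and pseudogene-style names and genes tied to sex. The second takes up to 4 members of each list with the smallest p. The last always takes TNF, IL1B, IL6, IL10, CXCL10, CD163, MRC1, MMP1, MMP9, TIMP1 and FCGR2B, and every called gene where fewer than 5 passed. Genes with at most 3 counts in a group are given as a bound or as a ratio with its interval.

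Alternatives were the fit without the block, RLE size factors, no filter on low counts, a filter of 1 CPM in at least 4 libraries, DESeq2 1.42.0, only the libraries of the groups compared, all 28 libraries in the fit, mitochondrial genes left out, each set left out in turn, and for lists the estimated correlation. For the agents against IgG, genes were also counted with the TNF group as reference in place of the IgG group. Thinning of all libraries to the lowest total, the mitochondrial share as a covariate and the fit without the TNF library of set C were added after seeing the data. Tables and figures were made with Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.

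The fits were tested on simulated data in which 66, 67 and 67 genes were changed by 1.5, 2 and 4-fold. In the simulated M1 vs M0 (14339 genes) 31.8%, 74.6% and 85.1% of these were recovered, with 8 false among 136 calls. In TNF vs M1 (14091 genes) the shares were 56.1%, 79.1% and 98.5% with 3 false among 159 calls. In adalimumab vs IgG (14065 genes) they were 37.9%, 85.1% and 97% with 5 of 152, and in adalimumab vs etanercept (14058 genes) 37.9%, 73.1% and 95.5% with 8 of 146. A planted list was called in each simulation, and 0 of 24 unchanged lists were called by camera in each. The simulated genes varied independently of one another, so these simulations do not test lists whose members vary together. In the data the estimated correlation reached, for example, 0.908 for type I interferon targets in M1 vs M0.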

Results

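To examine how blocking tumour necrosis factor (TNF) alters inflammatory macrophages and their expression of metalloproteinases, the series profiled human monocyte-derived macrophages by total RNA sequencing. Monocytes were cultured for 7 days with macrophage colony-stimulating factor (M-CSF, 20 ng/ml) to give resting M0 macrophages. The M1 group was stimulated with lipopolysaccharide (LPS, 10 ng/ml) and interferon gamma (IFN-γ, 20 ng/ml). The other 5 groups received this stimulus together with added TNF (100 ng/ml). It was given alone (the TNF group) or after it had been combined with a control immunoglobulin (the IgG group), adalimumab, etanercept or certolizumab pegol (each agent at 10 ug/ml). Adalimumab is a whole antibody against TNF, etanercept is a soluble TNF receptor fused to an antibody Fc part, and certolizumab pegol is an antibody fragment without an Fc part. Each of the 7 groups held 4 libraries, 1 from each of 4 sets named 1, A, C and D in the labels, which gave 28 libraries. The set was a block in the fits, so the p-values measure the spread left after differences between sets are removed. This spread is pooled over the groups of a fit. The labels do not say what a set is, so it may be technical.

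Libraries held 6107951 to 12985710 counts. The range was 7044838 to 8761036 in M0, 7541300 to 8806898 in M1, 8827558 to 10045249 in the TNF group and 8409464 to 11925347 in the IgG group. With adalimumab, etanercept and certolizumab it was 7352022 to 12985710, 6107951 to 11592137 and 7654005 to 10873000. Transcripts of the mitochondrial genome took 4.22% to 14.6% of the counts, with the highest share in the TNF library of set C. The first principal component of log2 expression carried 31.2% of the variance and placed the M0 libraries between 102.73 and 132.96, against -37.90 to 3.63 for the stimulated libraries. The second component carried 23.5% and placed the 6 stimulated libraries of set 1 between 68.23 and 81.99. The stimulated libraries of the other sets reached at most 5.18.

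**Figure D1:**
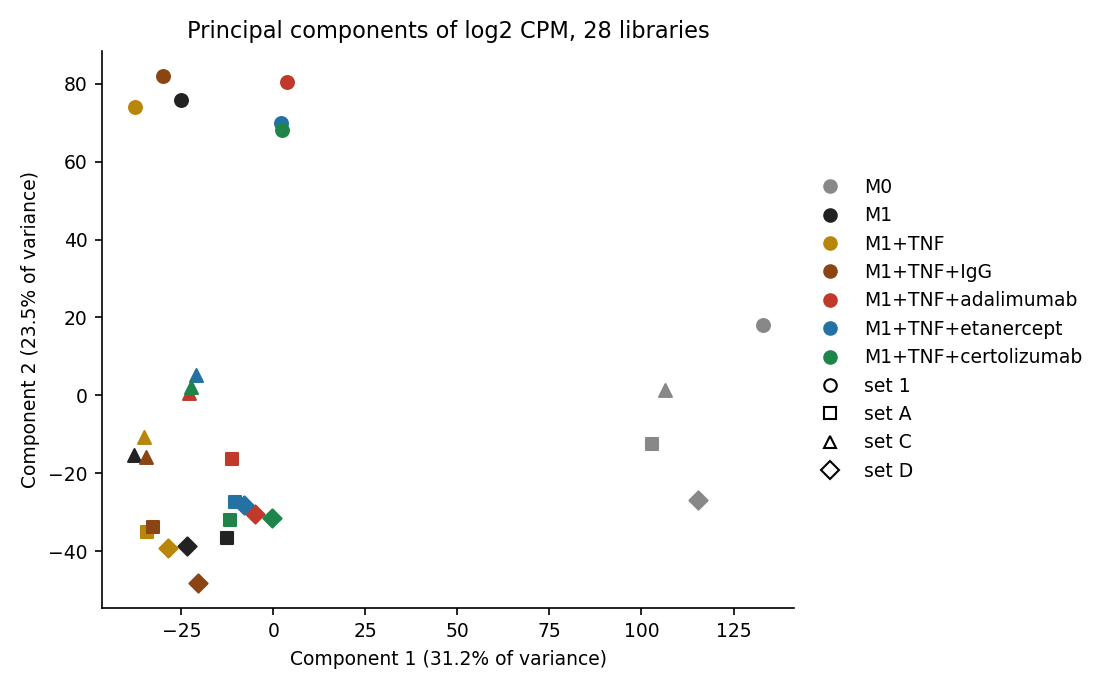
Scores of the 28 libraries on the first and second principal components of log2 expression, with colours for groups and symbols for sets. The M0 libraries lie at 102.73 or higher on the first component, and the stimulated libraries of set 1 lie at 68.23 or higher on the second.

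To define the response to LPS and IFN-γ, M1 was compared with M0 (4 libraries each). CCL19, a chemokine that guides dendritic cells and T cells, rose by a log2 fold change of 13.16 ± 0.55 (± standard error; adjusted p = 4.28e-15). CXCL9, a T cell attractant induced by IFN-γ, rose by 11.46 ± 0.36 (adjusted p = 3.51e-17). IDO1, which degrades tryptophan, rose by 10.84 ± 0.49 (adjusted p = 1.19e-14) and ACOD1, which makes the antimicrobial metabolite itaconate, by 10.75 ± 0.43 (adjusted p = 2.76e-15). MRC1, the mannose receptor, fell, at -4.38 ± 0.54 (adjusted p = 3.29e-07). So did TGFBI, an extracellular matrix protein, at -3.54 ± 0.27 (adjusted p = 1.31e-10), and F13A1, a chain of coagulation factor XIII, at -4.20 ± 0.43 (adjusted p = 2.01e-08). CXCL13, a B cell chemokine, had 8539 counts over the M1 libraries and 0 over the M0 libraries, at least 2720-fold higher against a floor of 3 counts over the group. SERPINB4, a protease inhibitor, had 533 counts against 0 and was at least 170-fold higher. TLR5, the flagellin receptor, had 3 counts against 694, a ratio of 0.00413 (95% counting interval 0.000849 to 0.0121). In all, 3574 genes rose and 3256 fell among 14546 tested, 1876 and 1443 of them by over 2-fold. Without the set as a block 4341 genes passed, and with only the 8 libraries of M0 and M1, 3896.

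Cytokine and chemokine genes rose together. Of the inflammatory cytokines, 16 rose, 0 fell and 4 did not pass (the same adjusted over the list alone). Their median log2 fold change was 2.82 (adjusted p = 2.96e-09 for the list in camera). EBI3, a subunit of interleukin 27, rose by 7.94 ± 0.47 (adjusted p = 1.69e-12) and IL15, which sustains natural killer cells, by 3.54 ± 0.25 (adjusted p = 2.53e-11). IL1B rose by 3.43 ± 0.72 (adjusted p = 0.000395) and TNF itself by 2.89 ± 0.35 (adjusted p = 2.68e-07). IL6 rose by 2.41 ± 0.71 (adjusted p = 0.00716), but without set 1 by 1.34 (adjusted p = 0.0587; range 2.09e-08 to 0.128). Such a range is that of the adjusted p over the alternatives. Of the chemokines, 15 rose, 0 fell and 4 did not pass (the same adjusted over the list alone), with a list adjusted p of 8.27e-10. CCL5 rose by 6.85 ± 0.49 (adjusted p = 4.82e-11) and CXCL10 by 8.14 ± 0.78 (adjusted p = 6.42e-09). Among anti-inflammatory regulators 19 rose, 6 fell and 4 did not pass (the same adjusted over the list alone), with a list adjusted p of 3.75e-09. IL10, the anti-inflammatory cytokine, rose by 2.82 ± 0.38 (adjusted p = 1.21e-06) and SOCS3, a brake on cytokine signalling, by 5.13 ± 0.33 (adjusted p = 7.79e-12).

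Interferon-induced genes rose. CD274, an inhibitory ligand for T cells, rose by 6.54 ± 0.18 (adjusted p = 4.46e-18) and APOL1 by 4.28 ± 0.18 (adjusted p = 6.03e-15). All 30 type I interferon targets tested rose, also adjusted over the list alone, with a median of 3.60 (list adjusted p = 2.16e-16). With an estimated correlation the adjusted p was 0.157 [6.03e-84 to 0.157], where square brackets give the range over a list's alternatives. ISG20, an antiviral exonuclease, rose by 5.92 ± 0.44 (adjusted p = 8.31e-11) and IFIH1, a sensor of viral RNA, by 3.36 ± 0.26 (adjusted p = 2.08e-10).

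Of the NF-kB feedback and TNF response genes, 31 rose, 1 fell and 0 did not pass (the same adjusted over the list alone), with a median of 2.54 (list adjusted p = 7.17e-41). TNFAIP3, which removes ubiquitin to end NF-kB signalling, rose by 3.53 ± 0.15 (adjusted p = 7.26e-15). CD40, a co-stimulatory receptor, rose by 4.23 ± 0.18 (adjusted p = 5.84e-15). In the TNF ligand and receptor system 17 rose, 1 fell and 4 did not pass (the same adjusted over the list alone), with a list adjusted p of 1.22e-05. The death receptor gene FAS rose by 3.65 ± 0.32 (adjusted p = 1.71e-09), while TNFRSF11A, the receptor that drives osteoclast formation, was at -3.30 ± 0.37 (adjusted p = 8.53e-08).

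Markers of alternative (M2) activation mostly fell. In this list 9 rose, 21 fell and 6 did not pass (9 rose and 22 fell adjusted over the list alone), with a median of -1.47 (list adjusted p = 0.0134). The call was lost without set A (adjusted p = 0.0631), without the block (0.0515) and with an estimated correlation, at an adjusted p of 0.111 [0.000133 to 0.111]. MS4A6A, a membrane protein of resting macrophages, was at -4.98 ± 0.33 (adjusted p = 1e-11), while CHI3L2, a chitinase-like protein, rose by 5.78 ± 0.39 (adjusted p = 1.53e-11). CD163, the haemoglobin scavenger receptor, was at -0.33 ± 0.28 (adjusted p = 0.341). Among Fc gamma receptors and their signalling genes 4 rose, 9 fell and 9 did not pass (4 rose and 10 fell adjusted over the list alone), with a list adjusted p of 0.186. SYK, the kinase downstream of these receptors, was at -1.81 ± 0.13 (adjusted p = 5.53e-11). FCGR2B, the inhibitory receptor, was at -1.54 ± 0.61 (adjusted p = 0.0427). Without sets 1, A, C and D in turn it was at -2.61, -0.88, -0.90 and -1.70 (adjusted p = 2.75e-05, 0.389, 0.34 and 0.0917; range 2.75e-05 to 0.72). It was also lost after thinning all libraries to the lowest total (adjusted p = 0.0587) and with the mitochondrial share as a covariate (0.052), and stood at 0.88 without the block.

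Proteases and their inhibitors moved in both directions. Of the matrix metalloproteinases, 7 rose, 2 fell and 5 did not pass (8 rose and 2 fell adjusted over the list alone), with a list adjusted p of 0.19. MMP12, the macrophage elastase, rose by 4.71 ± 0.48 (adjusted p = 1.96e-08) and MMP7 by 2.22 ± 0.30 (adjusted p = 1.49e-06), and MMP2, a gelatinase, was at -2.04 ± 0.27 (adjusted p = 9.86e-07). MMP1, a collagenase, rose by 3.06 ± 1.01 (adjusted p = 0.0153). Without sets 1, A, C and D in turn it was at 1.70, 2.88, 6.41 and 2.59 (adjusted p = 0.103, 0.0526, 0.000103 and 0.0887; range 7.1e-08 to 0.103). MMP9, the other gelatinase, was at -0.14 ± 0.26 (adjusted p = 0.683). Of the TIMP inhibitors and ADAM proteases, 10 rose, 8 fell and 2 did not pass (the same adjusted over the list alone), with a list adjusted p of 0.304. TIMP1 rose by 2.19 ± 0.31 (adjusted p = 2.75e-06) and the aggrecanase gene ADAMTS4 by 6.98 ± 0.58 (adjusted p = 6.21e-10), while TIMP2 was at -1.76 ± 0.16 (adjusted p = 3.5e-09). Among wound healing and growth factor genes 14 rose, 12 fell and 13 did not pass (15 rose and 13 fell adjusted over the list alone), with a list adjusted p of 0.947. SDC4, a cell surface proteoglycan, rose by 2.30 ± 0.17 (adjusted p = 6.24e-11).

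Metabolic genes also moved. All 13 metallothioneins and zinc transporters tested rose, also adjusted over the list alone, with a median of 4.50 (list adjusted p = 4.82e-12). Among them MT1M rose by 6.71 ± 0.47 (adjusted p = 2.53e-11) and MT2A by 5.19 ± 0.45 (adjusted p = 1.17e-09). Of the glycolysis and hypoxia genes, 16 rose, 2 fell and 11 did not pass (the same adjusted over the list alone). In camera the adjusted p was 0.00736, and 0.321 [0.000794 to 0.321] with an estimated correlation. PFKP, a phosphofructokinase, rose by 1.62 ± 0.19 (adjusted p = 1.4e-07). Of the cholesterol genes, 14 rose, 2 fell and 8 did not pass (15 rose and 4 fell adjusted over the list alone). Their list adjusted p was 0.00651, and 0.318 [0.000452 to 0.318] with an estimated correlation. Of the cell cycle genes, 0 rose, 20 fell and 4 did not pass (1 rose and 20 fell adjusted over the list alone), with a list adjusted p of 0.000928, and 0.194 [4.33e-06 to 0.194] with an estimated correlation. MKI67, a marker of dividing cells, was at -2.85 ± 0.31 (adjusted p = 4.49e-08).

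For MHC class II presentation 6 rose, 8 fell and 5 did not pass (7 rose and 8 fell adjusted over the list alone). The median was -0.16 and the mean 0.18, with a list adjusted p of 0.569 in the upward direction. CD80, a co-stimulatory ligand, rose by 5.71 ± 0.34 (adjusted p = 1.48e-12). Of the monocyte and dendritic cell markers, 6 rose, 2 fell and 3 did not pass (the same adjusted over the list alone). The list adjusted p was 3.02e-05, but 0.0651 without the block [5.75e-06 to 0.0651]. LAMP3, a marker of mature dendritic cells, rose by 8.95 ± 0.29 (adjusted p = 3.51e-17) and the chemokine receptor gene CCR7 by 8.59 ± 0.41 (adjusted p = 2.87e-14). Of the lymphocyte markers, 3 rose, 0 fell and 16 did not pass (the same adjusted over the list alone), with a list adjusted p of 0.563. PRF1, perforin, rose by 2.61 ± 0.24 (adjusted p = 2.9e-09) and NKG7, a cytotoxic granule protein, by 2.16 ± 0.38 (adjusted p = 5.65e-05). Of the platelet, erythroid and granulocyte markers, 1 rose, 1 fell and 8 did not pass (the same adjusted over the list alone). Their median was 0.17 and mean -0.01 (list adjusted p = 0.91, tested direction downward). The 13 mitochondrially encoded mRNAs had a median of -0.02 and a mean of 0.01 (list adjusted p = 0.83, tested direction downward). Of the stress and heat shock genes, 10 rose, 2 fell and 12 did not pass (the same adjusted over the list alone), with a list adjusted p of 0.0655.

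Whether added TNF changed stimulated macrophages further was addressed by comparing the TNF group with M1 (4 libraries each). A single gene passed, NIPAL4, a magnesium transporter gene, which rose by 1.38 ± 0.21 (adjusted p = 0.0205). Its level went from 12.9 ± 9.45 to 35.1 ± 23.7 CPM (counts scaled to library size, mean ± SD). NIPAL4 lies on chromosome 5, 157460019 to 157474717, plus strand (GRCh38), within the span of ADAM19 on the opposite strand, so its count is uncertain. Without sets A, C and D in turn the gene was at 1.18, 1.46 and 1.41 (adjusted p = 0.128, 0.262 and 0.611; range 5.83e-12 to 1). It was also lost without only the TNF library of set C (adjusted p = 0.362), with the mitochondrial share as a covariate (0.182) and without the block (1). The count of genes was 5 without set 1, 0 without set A, C or D, 0 without the block and 16 in DESeq2. An unadjusted p under 0.05 was reached by 890 of 14284 genes, somewhat more than the share of 0.05 that chance alone would give.

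No gene of the 25 lists passed over all genes, while 8 lists passed in camera at the preset correlation and 0 with an estimated one. NF-kB feedback and TNF response genes shifted upward, with a median of 0.16 (list adjusted p = 1.18e-06). Cell cycle genes shifted downward, with a median of -0.40 (list adjusted p = 2.32e-06). With an estimated correlation the adjusted p was 0.306 [1.46e-10 to 0.306] and 0.144 [4.42e-08 to 0.144]. These were the 2 calls that held without each set. Type I interferon targets shifted upward, with a median of 0.17 (list adjusted p = 1.39e-05), but their adjusted p was 0.0797 without set A and 0.66 [1.17e-09 to 0.66] with an estimated correlation. ICAM1, an adhesion molecule induced by TNF, was at 0.29 ± 0.10 (adjusted p = 0.571), TNFAIP3 at 0.30 ± 0.11 (adjusted p = 0.681) and IL10 at 0.87 ± 0.32 (adjusted p = 0.672). Mitochondrially encoded mRNAs shifted upward with a median of 0.38 (list adjusted p = 2.68e-06), but their adjusted p was 0.238 without set D and 0.515 [3e-15 to 0.515] with an estimated correlation. The mitochondrial share was 8.49 ± 4.4% in the TNF group and 6.54 ± 1.6% in M1. Of the cholesterol genes, 3 rose and 3 fell adjusted over the list alone (list adjusted p = 0.0179). The list's adjusted p was 0.946 without set C, 0.378 without set D and 0.544 [4.75e-08 to 0.946] with an estimated correlation. ABCA1, a cholesterol exporter, was at 0.68 ± 0.14 (adjusted p = 0.208) over all genes.

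As a control for adding immunoglobulin, the IgG group was compared with the TNF group (4 libraries each). No gene passed in edgeR, while DESeq2 called 155. An unadjusted p under 0.05 in edgeR was reached by 386 of 14284 genes, fewer than the share of 0.05 that chance alone would give. The inhibitory Fc receptor gene FCGR2B was at 0.01 ± 0.29 (adjusted p = 1), IL1B at 0.09 ± 0.31 (adjusted p = 1) and MMP9 at 0.07 ± 0.21 (adjusted p = 1). Of the 25 lists, 2 passed in camera and 0 with an estimated correlation. Without sets 1, A, C and D in turn the number was 1, 0, 3 and 1. Cell cycle genes shifted upward, with a median of 0.17 (list adjusted p = 0.0021), but their adjusted p was 0.688 [0.000105 to 0.688] with an estimated correlation, and 0.0662 without set A, 0.0664 without set D and 0.0504 without the block. No member passed over all genes, and 1 cell cycle gene rose adjusted over the list alone.

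Each agent was next compared with the IgG group (4 libraries each), which had received the same dose of TNF. Values for the agents are given in the order adalimumab, etanercept and certolizumab. MS4A6A, which LPS and IFN-γ had lowered, rose by 3.89 ± 0.33, 3.80 ± 0.34 and 4.37 ± 0.33 (highest adjusted p = 3.77e-07). MERTK, the receptor kinase for uptake of apoptotic cells, rose by 2.45 ± 0.23, 1.99 ± 0.23 and 2.30 ± 0.23 (highest adjusted p = 7.75e-06). TGFBI rose by 2.16 ± 0.25, 2.14 ± 0.25 and 2.29 ± 0.25 (highest adjusted p = 7.82e-06), FGL2, a prothrombinase of immune cells, by 2.87 ± 0.34, 3.11 ± 0.34 and 3.24 ± 0.34 (highest adjusted p = 5.76e-06) and GCNT1, an O-glycan branching enzyme, by 2.99 ± 0.27, 3.06 ± 0.27 and 3.30 ± 0.27 (highest adjusted p = 3.77e-07). FSTL3, an activin-binding protein, fell, at -3.54 ± 0.36, -3.74 ± 0.37 and -2.92 ± 0.34 (highest adjusted p = 7.4e-06). G0S2, an inhibitor of fat breakdown, fell, at -3.11 ± 0.36, -3.13 ± 0.36 and -3.04 ± 0.36 (highest adjusted p = 7.71e-06). ADORA3, an adenosine receptor gene that shares its locus and strand with TMIGD3, had 196, 94 and 185 counts over the 4 libraries of each agent against 3 with IgG. The ratios were 60.5 (95% counting interval 20.4 to 296), 33.5 (11.1 to 165) and 59.7 (20.1 to 292). MS4A6A (GRCh38 chromosome 11, 60172014 to 60184666, minus strand) averaged 61.4 ± 25.5 CPM in M0 and 1.35 ± 0.833 with IgG (mean ± SD). With the agents it averaged 19.3 ± 12.5, 17.9 ± 8.77 and 27.2 ± 13.5.

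With adalimumab 1291 genes rose and 942 fell among 14284 tested, 357 and 241 of them by over 2-fold. With etanercept 956 rose and 738 fell (265 and 207 by over 2-fold), and with certolizumab 1023 rose and 712 fell (277 and 218 by over 2-fold). These counts rest on pairing the libraries by set. Without the block 130, 86 and 84 genes passed, and of the 105, 97 and 101 called genes chosen for naming, 21, 19 and 15 stayed past the threshold. Leaving out set A, C or D lowered the adalimumab count from 2233 to 1345, 1119 or 989. Leaving out C or D lowered the etanercept count from 1694 to 853 or 842 and the certolizumab count from 1735 to 986 or 908. With the M0 libraries in the fit the counts were 1348, 986 and 1057. With the TNF group as reference in place of the IgG group they were 2484, 1938 and 2028.

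**Figure D2:**
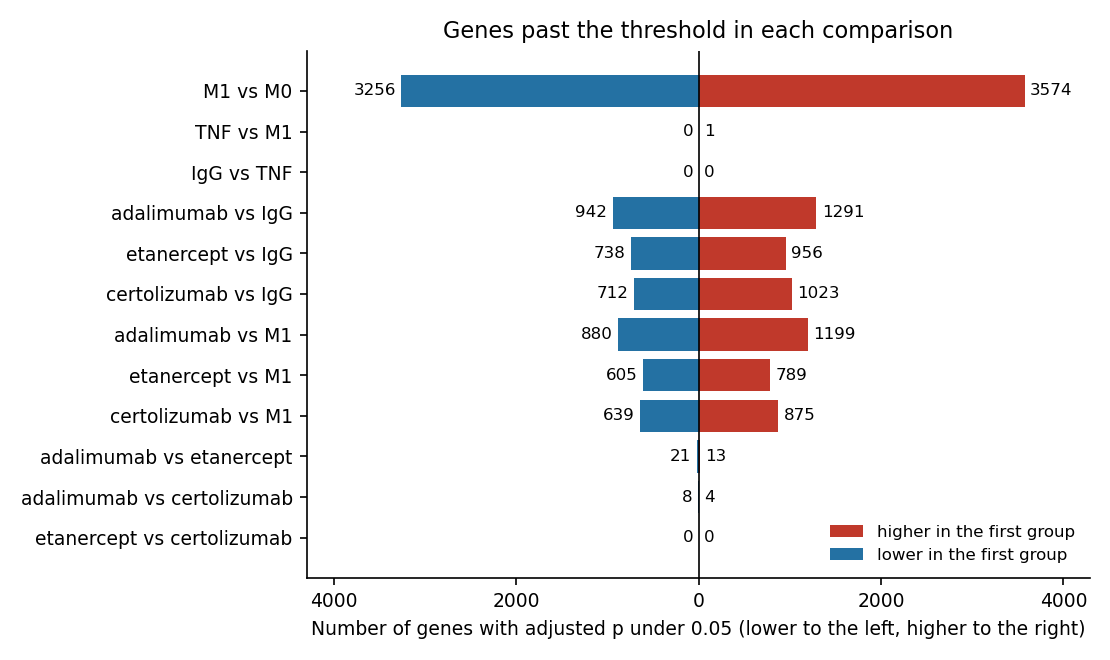
Number of genes higher (bars to the right) and lower (bars to the left) at an adjusted p under 0.05 in each of 12 comparisons, on a linear axis. Each agent changed between 1394 and 2233 genes against M1 or IgG, while the agents differed from one another in at most 34.

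NF-kB feedback and TNF response genes fell with every agent. Of 32 tested, none rose and 23, 21 and 22 fell (1, 1 and 1 rose and 26, 24 and 26 fell adjusted over the list alone). Their medians were -0.65, -0.56 and -0.59, with a list adjusted p of 2.29e-26, 2.08e-24 and 1.58e-26. NFKB2, a subunit of the transcription factor, was at -1.0 ± 0.11, -0.89 ± 0.11 and -0.90 ± 0.11 (highest adjusted p = 1.34e-05). TNIP1, a partner of TNFAIP3, was at -0.92 ± 0.09, -0.88 ± 0.09 and -0.99 ± 0.09 (highest adjusted p = 1.61e-06), and TNFAIP6, a hyaluronan-binding protein induced by TNF, at -1.40 ± 0.17, -1.53 ± 0.17 and -1.59 ± 0.17 (highest adjusted p = 8.04e-06). Markers of alternative activation rose on balance. Of 36 tested, 19, 16 and 17 rose and 3, 4 and 4 fell (21, 17 and 19 rose and 4, 6 and 5 fell adjusted over the list alone), with medians of 0.83, 0.65 and 0.83 (list adjusted p = 4.7e-08, 1.62e-06 and 5.59e-08). CLEC7A, the receptor for fungal beta-glucan, rose by 1.57 ± 0.18, 1.32 ± 0.18 and 1.5 ± 0.18 (highest adjusted p = 4.6e-05). Among 22 Fc gamma receptors and their signalling genes 11, 12 and 13 rose and none fell (12, 15 and 16 rose and none fell adjusted over the list alone), with a list adjusted p of 2.09e-09, 2.48e-12 and 6.93e-13. FCGR3A, an activating receptor whose reads can be shared with FCGR3B, rose by 1.51 ± 0.19, 1.55 ± 0.19 and 1.57 ± 0.19 (highest adjusted p = 1.29e-05) and SYK by 0.92 ± 0.09, 1.05 ± 0.09 and 1.18 ± 0.09 (highest adjusted p = 1.25e-06). These 3 lists passed in every alternative. With an estimated correlation the adjusted p was 0.00459 [5.71e-27 to 0.00459], 0.00641 [7.71e-26 to 0.00641] and 0.00307 [1.06e-28 to 0.00307] for NF-kB feedback genes, 0.00459 [1.62e-09 to 0.00459], 0.00829 [6.86e-08 to 0.00829] and 0.00307 [6.26e-09 to 0.00307] for alternative markers and 0.00459 [2.33e-09 to 0.00459], 0.0026 [1.66e-12 to 0.0026] and 0.00198 [8.4e-13 to 0.00198] for Fc gamma receptor genes. No other list held for an agent against IgG with an estimated correlation.

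CD163 rose by 1.39 ± 0.28, 1.04 ± 0.28 and 1.03 ± 0.28 (highest adjusted p = 0.0164). Without sets C and D it was at 0.99 and 0.85 (adjusted p = 0.114 and 0.131; range 1.93e-17 to 0.382) with etanercept and 0.98 and 0.92 (adjusted p = 0.112 and 0.0949; range 7.22e-19 to 0.378) with certolizumab. MRC1 rose by 1.73 ± 0.39, 1.5 ± 0.39 and 1.52 ± 0.39 (highest adjusted p = 0.012). For etanercept it was at 0.97 and 1.69 (adjusted p = 0.00315 and 0.0548; range 9.11e-27 to 0.658) without sets 1 and D, and for certolizumab at 0.99 (adjusted p = 0.00276; range 7.72e-30 to 0.624) without set 1. FCGR2B was at 1.26 ± 0.27, 0.84 ± 0.28 and 1.07 ± 0.28 (adjusted p = 0.00279, 0.0535 and 0.0108). For certolizumab it was at 0.97 and 0.88 (adjusted p = 0.0743 and 0.0689; range 1.66e-09 to 0.991) without sets C and D. Of 29 anti-inflammatory regulators, 10, 5 and 6 rose and 5, 6 and 6 fell (13, 10 and 8 rose and 7, 6 and 7 fell adjusted over the list alone), with a list adjusted p of 0.107, 0.433 and 0.475. IL10 fell, at -1.76 ± 0.33, -2.63 ± 0.36 and -2.28 ± 0.35 (highest adjusted p = 0.000754), while TSC22D3, a regulator induced by glucocorticoids, rose by 0.98 ± 0.11, 0.98 ± 0.11 and 0.87 ± 0.11 (highest adjusted p = 1.28e-05).

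Of 20 inflammatory cytokine genes, 1, 0 and 1 rose and 5, 5 and 8 fell (1, 1 and 1 rose and 8, 5 and 8 fell adjusted over the list alone). In camera they shifted downward (list adjusted p = 0.00796, 0.0174 and 0.000152), but the adjusted p was 0.45 [0.000532 to 0.45], 0.432 [0.00282 to 0.432] and 0.172 [1.42e-06 to 0.172] with an estimated correlation. The calls were lost without the block for each agent (adjusted p = 0.397, 0.342 and 0.0637) and without set 1 for adalimumab (0.055) and etanercept (0.302). EBI3 was at -1.66 ± 0.13, -1.40 ± 0.13 and -1.32 ± 0.13 (highest adjusted p = 1.19e-06) and IL18, a cytokine matured by caspase 1, at -0.85 ± 0.15, -0.83 ± 0.16 and -0.76 ± 0.15 (highest adjusted p = 0.00172). IL1B was at -1.34 ± 0.32, -1.16 ± 0.32 and -1.66 ± 0.32 (highest adjusted p = 0.018). For adalimumab it was at -1.06 and -1.13 (adjusted p = 0.051 and 0.0948; range 5.6e-32 to 0.956) without sets C and D, and for etanercept at -1.04 and -0.98 (adjusted p = 0.0607 and 0.169; range 4.9e-25 to 0.96) without sets 1 and D. IL6 was at 0.13 ± 0.40, 0.29 ± 0.40 and -0.32 ± 0.41 (lowest adjusted p = 0.708) and TNF at 0.30 ± 0.27, 0.34 ± 0.27 and 0.14 ± 0.27 (lowest adjusted p = 0.507).

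Chemokine genes moved in both directions. Of 19 tested, 3, 3 and 2 rose and 4, 4 and 5 fell (4, 4 and 4 rose and 4, 7 and 8 fell adjusted over the list alone), with a list adjusted p of 0.796, 0.331 and 0.113. CCL20, which attracts Th17 cells, was at -1.62 ± 0.31, -2.20 ± 0.33 and -2.08 ± 0.33 (highest adjusted p = 0.000873). CCL7, a monocyte attractant, rose by 1.76 ± 0.26, 1.33 ± 0.26 and 1.36 ± 0.26 (highest adjusted p = 0.00152). CXCL10 rose by 1.03 ± 0.32, 1.29 ± 0.32 and 1.25 ± 0.32 (highest adjusted p = 0.0302). For adalimumab it was at 1.10, 0.70, 0.91 and 0.92 (adjusted p = 0.0886, 0.24, 0.219 and 0.0581; range 6.84e-19 to 0.545) without sets A, C and D and with the mitochondrial share as a covariate. For etanercept it was at 1.16 (adjusted p = 0.111; range 6.19e-28 to 0.49) without set D, and for certolizumab at 1.10 and 1.28 (adjusted p = 0.0615 and 0.0765; range 8.17e-28 to 0.606) without sets C and D.

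Of 30 type I interferon targets, 16, 2 and 3 rose and none fell (24, 1 and 2 rose and none fell adjusted over the list alone). Camera gave a list adjusted p of 1.5e-10, 0.0101 and 0.000222, and 0.45 [4.86e-27 to 0.45], 0.652 [2.61e-08 to 0.652] and 0.631 [2.55e-08 to 0.631] with an estimated correlation. The etanercept call was lost without set C (0.155) or D (0.249). With adalimumab IFIT2, an inhibitor of viral translation, rose by 1.79 ± 0.28 (adjusted p = 0.000112) and RSAD2, viperin, by 1.03 ± 0.17 (adjusted p = 0.000163). CXCL9 fell with adalimumab, at -0.82 ± 0.16 (adjusted p = 0.00094), while SOCS1, a relative of SOCS3, rose by 1.0 ± 0.14 (adjusted p = 6.31e-05) with etanercept and 0.93 ± 0.14 (adjusted p = 0.00012) with certolizumab. Of 19 MHC class II genes, 5, 13 and 12 rose and 2, 0 and 0 fell (8, 13 and 13 rose and 3, 0 and 1 fell adjusted over the list alone). Their list adjusted p was 0.0234, 1.28e-10 and 4.85e-07, and 0.573 [0.00244 to 0.573], 0.0755 [1.01e-12 to 0.0755] and 0.172 [1.28e-10 to 0.172] with an estimated correlation. For adalimumab it was 0.417 without the block and 0.113 without set D. CIITA, the master activator of these genes, rose by 1.43 ± 0.30, 2.42 ± 0.31 and 2.21 ± 0.30 (highest adjusted p = 0.00217).

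Of 14 matrix metalloproteinases tested, 3, 0 and 0 rose and 0, 1 and 1 fell (3, 0 and 0 rose and 0, 1 and 0 fell adjusted over the list alone), with a list adjusted p of 0.151, 0.331 and 0.473. With adalimumab MMP10, stromelysin 2, rose by 1.38 ± 0.30 (adjusted p = 0.00282) and MMP19 by 0.87 ± 0.12 (adjusted p = 2.5e-05). MMP3, stromelysin 1, rose with adalimumab by 1.60 ± 0.47 (adjusted p = 0.0218). Without sets 1, C and D, with the mitochondrial share as a covariate and in DESeq2 it was at 0.57, 1.75, 1.70, 1.34 and 0.98 (adjusted p = 0.529, 0.05, 0.0657, 0.0665 and 0.369; range 6.44e-16 to 0.812). With certolizumab MMP3 was at -1.68 ± 0.53 (adjusted p = 0.0398). Without sets 1, A, C and D in turn and after thinning it was at -2.86, -1.14, -1.62, -1.66 and -1.63 (adjusted p = 0.00969, 0.113, 0.11, 0.122 and 0.0635; range 7.64e-15 to 0.988). MMP1 was at 1.03 ± 0.43, -0.60 ± 0.46 and -1.05 ± 0.47 (lowest adjusted p = 0.112), MMP9 at 0.47 ± 0.21, -0.12 ± 0.21 and -0.11 ± 0.21 (lowest adjusted p = 0.154) and TIMP1 at 0.15 ± 0.18, -0.10 ± 0.18 and -0.17 ± 0.18 (lowest adjusted p = 0.63). Of 19 TIMP and ADAM genes, 7, 4 and 6 rose and 2, 2 and 2 fell (8, 8 and 8 rose and 2, 2 and 2 fell adjusted over the list alone), with a list adjusted p of 0.0643, 0.2 and 0.178. ADAMTS4 fell, at -2.90 ± 0.39, -2.64 ± 0.39 and -2.04 ± 0.36 (highest adjusted p = 0.000463).

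Of 37 wound healing and growth factor genes, 8, 3 and 4 rose and 4, 4 and 3 fell (9, 6 and 4 rose and 4, 4 and 3 fell adjusted over the list alone), with a list adjusted p of 0.236, 0.913 and 0.989. PLAU, the urokinase protease, rose by 1.11 ± 0.15, 0.96 ± 0.15 and 1.03 ± 0.15 (highest adjusted p = 0.000142), and VEGFA, the angiogenic factor, fell, at -1.71 ± 0.18, -1.26 ± 0.18 and -1.15 ± 0.18 (highest adjusted p = 0.000121). Of 13 metallothioneins and zinc transporters, 1, 0 and 0 rose and 6, 4 and 7 fell (1, 1 and 1 rose and 7, 5 and 10 fell adjusted over the list alone). As a list they shifted downward (list adjusted p = 0.00028, 0.00239 and 1.85e-07), and the adjusted p was 0.45 [1.12e-08 to 0.45], 0.441 [1.2e-06 to 0.441] and 0.172 [1.06e-13 to 0.172] with an estimated correlation. Without the block it was 0.167 for adalimumab and 0.18 for etanercept, and 0.114 for etanercept without set 1. Of 29 glycolysis and hypoxia genes, 2, 1 and 1 rose and 5, 10 and 4 fell (2, 3 and 1 rose and 5, 11 and 5 fell adjusted over the list alone). Their list adjusted p was 0.107, 0.000593 and 0.0685, and 0.432 [5.05e-05 to 0.432] for etanercept with an estimated correlation. Of 24 cholesterol genes, 2, 1 and 2 rose and 1, 2 and 3 fell (2, 2 and 2 rose and 1, 4 and 3 fell adjusted over the list alone). For this list the adjusted p was 0.484, 0.0169 and 0.0516, and for etanercept 0.46 [0.00133 to 0.46] with an estimated correlation and 0.281 without set 1. HMGCS1, an enzyme of the mevalonate pathway, was at -0.88 ± 0.21, -1.09 ± 0.21 and -1.04 ± 0.21 (highest adjusted p = 0.00494). Of 24 cell cycle genes, 1, 1 and 2 rose and none fell (the same adjusted over the list alone), with a list adjusted p of 0.209, 0.331 and 0.224. MKI67 rose by 1.26 ± 0.21, 1.17 ± 0.21 and 1.07 ± 0.21 (highest adjusted p = 0.00141).

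Of 20 lymphocyte markers, none rose and 6, 4 and 3 fell (none rose and 6, 5 and 3 fell adjusted over the list alone). As a list they had an adjusted p of 0.00322, 0.00892 and 0.000197, and 0.45 [0.000399 to 0.45], 0.441 [0.000619 to 0.441] and 0.357 [6.13e-06 to 0.357] with an estimated correlation. The calls were lost without the block for adalimumab (0.224) and etanercept (0.258), and without set C for etanercept (0.174). NKG7 was at -0.86 ± 0.15, -0.86 ± 0.15 and -1.18 ± 0.15 (highest adjusted p = 0.000445). The list adjusted p was 0.979, 0.918 and 0.552 for platelet, erythroid and granulocyte markers, 0.27, 0.918 and 0.685 for mitochondrially encoded mRNAs and 0.945, 0.433 and 0.685 for stress and heat shock genes. The mitochondrial share was 7.84 ± 2% with IgG, 6.8 ± 1.4% with adalimumab, 7.9 ± 2.3% with etanercept and 7.37 ± 2.2% with certolizumab (mean ± SD, n = 4).

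How far the responses to the agents resembled one another was examined across the 14284 genes, which are not independent replicates. Of the genes called for both adalimumab and etanercept, 705 rose and 525 fell with both and 2 went opposite ways. For adalimumab and certolizumab the numbers were 773, 526 and 1, and for etanercept and certolizumab 773, 521 and 0. Independent lists of these sizes would share 86.4 and 48.7, 92.5 and 47, and 68.5 and 36.8 genes. Unchanged groups simulated against the same IgG libraries shared 0 calls over 20 simulations. Adjusted tests of unchanged groups seldom give calls that could be shared. This 0 therefore does not measure how far the shared IgG libraries align the calls of changed groups. In all, 633 genes rose and 436 fell with all 3 agents. The correlation of log2 fold changes was 0.771, 0.788 and 0.809, against 0.5, 0.509 and 0.501 in the simulations. With the IgG libraries split between the comparisons it was 0.441 (0.362 to 0.49 over 6 splits), 0.465 (0.41 to 0.537) and 0.454 (0.349 to 0.513). In these splits each agent also had only 2 libraries, and the 2 agents came from different sets. The lower values therefore do not measure the shared IgG libraries alone. Over all libraries the covariance was 0.191, 0.197 and 0.192 against a simulated 0.042, 0.0424 and 0.0422, which leaves differences of 0.149, 0.154 and 0.15. In the splits, computed from differences of log2 CPM, the mean covariance was 0.123, 0.13 and 0.122.

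The agents were also compared with M1, which had received no added TNF (4 libraries each). MS4A6A rose by 3.30 ± 0.32, 3.22 ± 0.32 and 3.79 ± 0.32 (highest adjusted p = 3.82e-06) and MERTK by 2.24 ± 0.23, 1.77 ± 0.23 and 2.09 ± 0.23 (highest adjusted p = 4.73e-05). NAIP, a sensor of bacterial flagellin, rose by 2.04 ± 0.26, 1.75 ± 0.26 and 2.07 ± 0.26 (highest adjusted p = 0.000187), and NFKB2 fell, at -0.96 ± 0.11, -0.84 ± 0.11 and -0.85 ± 0.11 (highest adjusted p = 4.82e-05). With adalimumab MMP10 rose by 2.25 ± 0.32 (adjusted p = 6.51e-05), MMP3 by 2.60 ± 0.49 (adjusted p = 0.000909) and MMP19 by 1.18 ± 0.12 (adjusted p = 1.75e-06). MMP1 rose with adalimumab by 1.89 ± 0.47 (adjusted p = 0.00865), but without set 1 by 1.39 (adjusted p = 0.0827; range 1.42e-36 to 0.761). The counts were 1199 higher and 880 lower with adalimumab, 789 and 605 with etanercept and 875 and 639 with certolizumab. Without the block 80, 29 and 29 genes passed, with only the 8 libraries compared 462, 794 and 659, and with M0 in the fit 1113, 732 and 770. Without set A, C or D the adalimumab count of 2079 became 1372, 1150 or 777. Without C or D the etanercept count of 1394 became 463 or 402 and the certolizumab count of 1514 became 748 or 489.

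The list tests against M1 gave 7, 10 and 11 calls, and 3 for each agent with an estimated correlation. Without set C the adalimumab number was 11. The 3 lists that held in every alternative were those that held against IgG. Of the NF-kB feedback genes, none rose and 19, 17 and 19 fell (none rose and 22, 22 and 24 fell adjusted over the list alone), with a list adjusted p of 3.4e-17, 5.78e-16 and 1.04e-17. Of the alternative markers, 20, 16 and 17 rose and 4, 5 and 5 fell (20, 22 and 22 rose and 6, 7 and 6 fell adjusted over the list alone), with a list adjusted p of 1.85e-07, 2.14e-06 and 5.4e-08. Of the Fc gamma receptor genes, 9, 9 and 10 rose and none fell (12, 15 and 15 rose and 1, 0 and 0 fell adjusted over the list alone), with a list adjusted p of 1.39e-05, 2.66e-08 and 1.99e-08. Of the type I interferon targets, 21, 5 and 9 rose and none fell (27, 7 and 14 rose and none fell adjusted over the list alone). Their list adjusted p was 8.42e-17, 2.93e-06 and 1.99e-08, and 0.271 [6.24e-38 to 0.271], 0.554 [1.12e-14 to 0.554] and 0.467 [3.78e-15 to 0.467] with an estimated correlation. RSAD2 rose by 1.33 ± 0.17 and 0.87 ± 0.17 (highest adjusted p = 0.00134) with adalimumab and certolizumab. Of the matrix metalloproteinases with adalimumab, 4 rose, 1 fell and 9 did not pass (4 rose and 2 fell adjusted over the list alone). The list adjusted p was 0.0392, but 0.271 [0.00383 to 0.271] with an estimated correlation, and 0.0951 without set 1, 0.12 without set A and 0.197 without the block.

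In the MHC class II list 11 and 8 rose and none fell (13 and 11 rose and 0 and 1 fell adjusted over the list alone) against M1 with etanercept and certolizumab. Its list adjusted p was 2.08e-08 and 2.79e-05, and 0.134 [1.1e-11 to 0.134] and 0.342 [2.27e-09 to 0.342] with an estimated correlation. CIITA rose by 1.83 ± 0.30 and 1.62 ± 0.30 (highest adjusted p = 0.00111). Of the cholesterol genes, 2 and 5 rose and 9 and 11 fell (5 and 5 rose and 14 and 16 fell adjusted over the list alone) with these 2 agents. As a list they shifted downward (list adjusted p = 0.000301 and 0.00157), and the adjusted p was 0.421 [2.9e-05 to 0.421] and 0.43 [0.000283 to 0.43] with an estimated correlation. Metallothioneins shifted downward against M1 with adalimumab, etanercept and certolizumab (list adjusted p = 0.00317, 0.0114 and 1.81e-06), where 1, 1 and 1 rose and 5, 4 and 6 fell (1, 1 and 1 rose and 5, 4 and 10 fell adjusted over the list alone), and their adjusted p was 0.607 [8.79e-05 to 0.607], 0.554 [0.000161 to 0.554] and 0.342 [2.98e-09 to 0.342] with an estimated correlation. Without the block it was 0.278 and 0.362 for adalimumab and etanercept, and without set 1 0.0565 and 0.217. Mitochondrially encoded mRNAs shifted upward with etanercept and certolizumab (list adjusted p = 0.000438 and 0.00271), and their adjusted p was 0.554 [2.22e-05 to 0.554] and 0.57 [0.000182 to 0.57] with an estimated correlation. Without set D the certolizumab value was 0.252, and for adalimumab the list adjusted p was 0.0808. The mitochondrial share was 7.9 ± 2.3% with etanercept and 7.37 ± 2.2% with certolizumab against 6.54 ± 1.6% in M1. Of 20 lymphocyte markers, none rose and 3, 3 and 3 fell (none rose and 3, 3 and 4 fell adjusted over the list alone) with the 3 agents. Their list adjusted p was 0.0808, 0.183 and 0.0148, and for certolizumab 0.537 [0.0036 to 0.663] with an estimated correlation, 0.162 without the block and 0.663 without set A.

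Finally the agents were compared with one another (4 libraries each). Adalimumab differed from etanercept in 34 genes, 13 higher and 21 lower, and from certolizumab in 12, 4 higher and 8 lower. CXCL9 was lower with adalimumab than with etanercept, at -1.32 ± 0.16 (adjusted p = 0.000407). GREM1, an antagonist of bone morphogenetic proteins, was higher, at 1.30 ± 0.18 (adjusted p = 0.00133). Against certolizumab CXCL9 was at -0.93 ± 0.16 (adjusted p = 0.0191) and GREM1 at 1.23 ± 0.18 (adjusted p = 0.00562). The GREM1 call against certolizumab was lost without sets A and D, at 1.25 and 1.38 (adjusted p = 0.18 and 0.0583; range 4.24e-20 to 0.551). The CXCL9 call was lost without sets A, C and D, at -0.94, -0.88 and -0.87 (adjusted p = 0.145, 0.163 and 0.212; range 8.46e-15 to 1). GREM1 (GRCh38 chromosome 15, 32717974 to 32745107, plus strand) averaged 115 ± 40.9 CPM with IgG and 314 ± 134, 122 ± 12.6 and 129 ± 14.3 with the agents (mean ± SD). CXCL9 (chromosome 4, 76001275 to 76007488, minus strand) averaged 2480 ± 1580 with IgG and 1280 ± 669, 3430 ± 2270 and 2550 ± 1400 with the agents.

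The 34 genes against etanercept and 12 against certolizumab became 0 and 0 without the block, 266 and 262 in DESeq2, and 103 and 1 with only the 8 libraries compared. Leaving out set A, C or D gave 7, 10 and 7 genes against etanercept. Leaving out set 1, A, C or D gave 36, 1, 4 and 1 against certolizumab.

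The metalloproteinase list was higher with adalimumab than with either other agent. Against etanercept 2 rose, 0 fell and 12 did not pass (8 rose and 1 fell adjusted over the list alone), and against certolizumab 2 rose, 0 fell and 12 did not pass (5 rose and 1 fell adjusted over the list alone). The list adjusted p was 5.96e-06 and 1.61e-05, and with an estimated correlation 0.025 [3.46e-06 to 0.0679] and 0.0279 [1.58e-05 to 0.195]. Without the block it was 0.0679 and 0.195. MMP3 was higher than with certolizumab by 3.29 ± 0.51 (adjusted p = 0.00589), but without set D by 3.35 (adjusted p = 0.0583; range 7.93e-59 to 1). Against etanercept it was at 1.97 ± 0.48 (adjusted p = 0.0953). MMP10 was higher than with etanercept by 1.63 ± 0.31 (adjusted p = 0.0268). Without sets 1, A, C and D in turn this became 1.06, 1.96, 1.71 and 1.81 (adjusted p = 0.137, 0.0781, 0.0814 and 0.123; range 2.18e-21 to 1). Against certolizumab MMP10 was higher by 1.82 ± 0.32 (adjusted p = 0.0209), and without sets 1, A and D by 1.36, 1.70 and 1.93 (adjusted p = 0.0678, 0.213 and 0.104; range 9.17e-25 to 1). MMP3 (chromosome 11, 102835801 to 102843803, minus strand) averaged 28.3 ± 44.2 CPM with IgG and 155 ± 287, 17.6 ± 24.2 and 13.9 ± 26 with the agents, with 586 in the adalimumab library of set 1. MMP10 (chromosome 11, 102770503 to 102780628, minus strand) averaged 24.3 ± 26.3 with IgG and 81.1 ± 112, 17.1 ± 14.3 and 16.5 ± 16.6 with the agents.

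**Figure D3:**
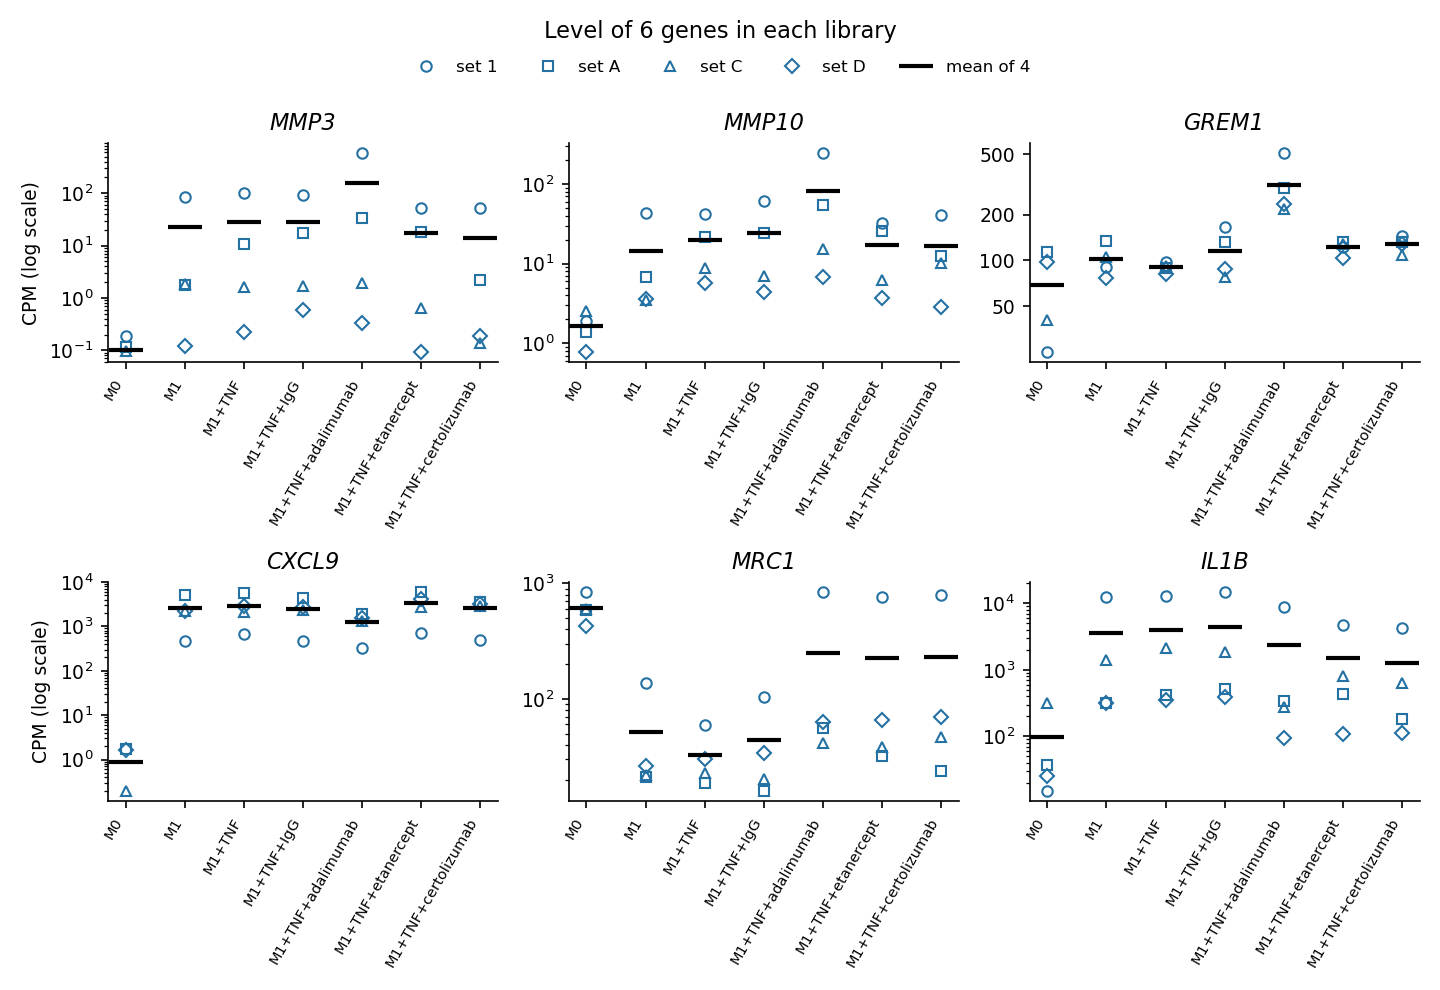
CPM of MMP3, MMP10, GREM1, CXCL9, MRC1 and IL1B in each library on a log axis, by group, with symbols for sets and a black bar at the mean of 4 libraries. Libraries at 0 (MMP3 in M0 of set D, CXCL9 in M0 of set 1) are not drawn, and the adalimumab library of set 1 lies at 586 for MMP3.

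The guanylate-binding protein gene GBP5 was at -1.17 ± 0.19 (adjusted p = 0.00716) against etanercept, and without sets A and C at -1.10 and -1.21 (adjusted p = 0.0781 and 0.0585; range 3.28e-20 to 1). MHC class II genes shifted downward against etanercept and certolizumab (list adjusted p = 9.67e-10 and 2.3e-05), and the adjusted p was 0.123 [1.19e-11 to 0.123] and 0.56 [1.02e-10 to 0.56] with an estimated correlation. No member passed over all genes, and adjusted over the list alone 1 was higher and 9 lower than with etanercept, and 0 and 0 than with certolizumab, where the list adjusted p was 0.0983 without set 1. Type I interferon targets shifted upward against both (list adjusted p = 5.2e-12 and 7.65e-08). No member passed over all genes, and 14 and 0 rose adjusted over the list alone. With an estimated correlation the adjusted p was 0.455 [2.08e-29 to 0.455] and 0.563 [5.59e-32 to 0.563]. In all, 7 lists passed against etanercept and 5 against certolizumab (9 without set C or D), and 2 and 1 with an estimated correlation.

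**Figure D4:**
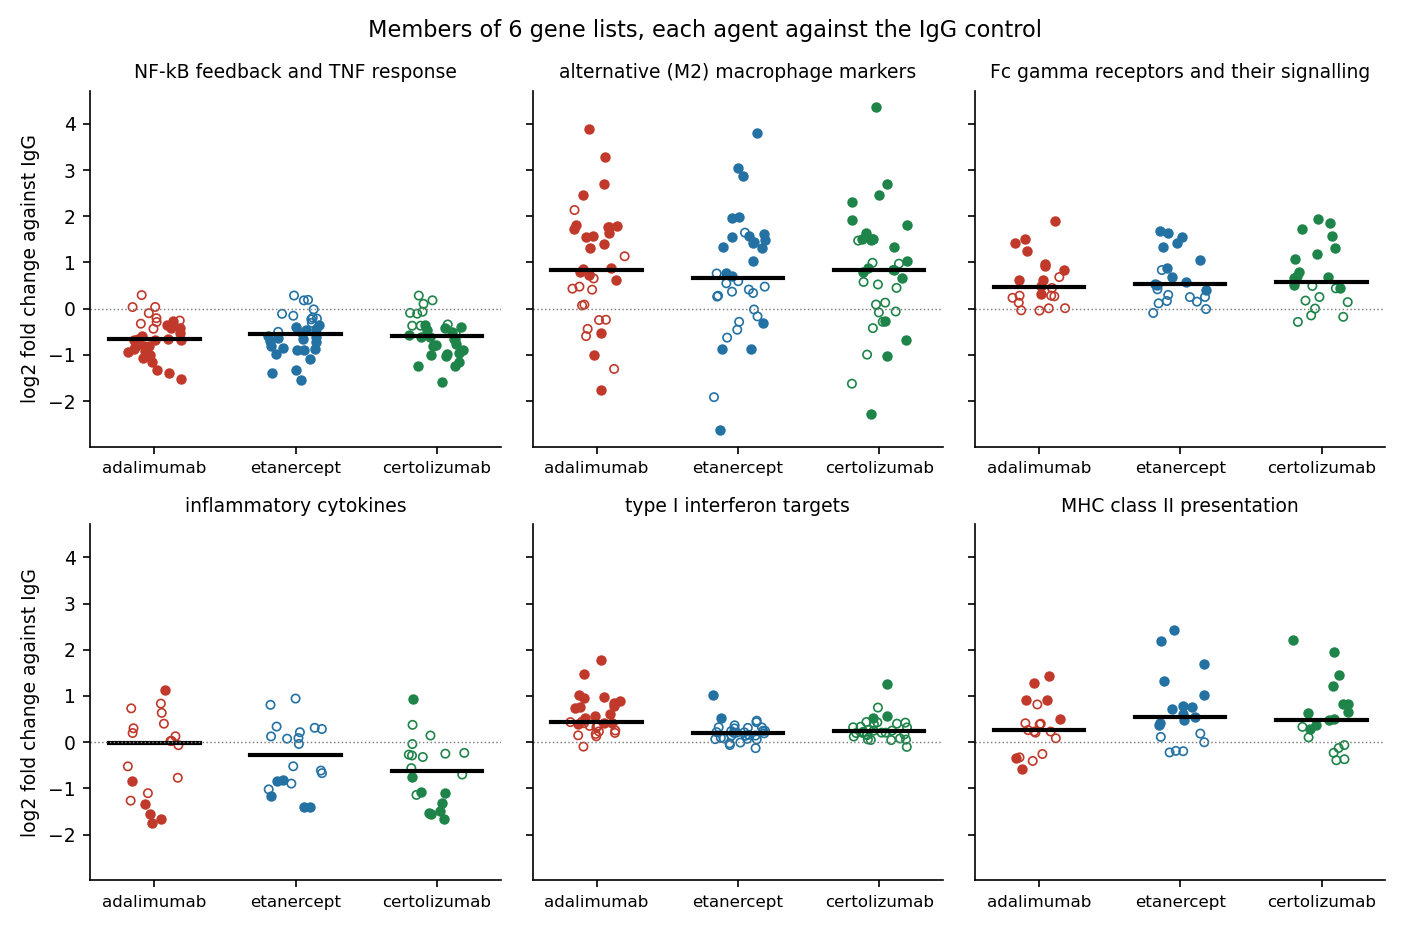
Log2 fold changes against IgG of the members of 6 gene lists, for adalimumab, etanercept and certolizumab. Each point is a gene, filled points have an adjusted p under 0.05 and black bars mark medians, which for NF-kB feedback and TNF response genes lie at -0.65, -0.56 and -0.59.

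Between etanercept and certolizumab no gene passed in edgeR, while DESeq2 called 170. Of 14284 genes 458 had an unadjusted p under 0.05 in edgeR, fewer than the share of 0.05 that chance alone would give. CXCL9 was at 0.38 ± 0.16 (adjusted p = 0.999), MMP3 at 1.32 ± 0.54 (adjusted p = 0.999) and MS4A6A at -0.57 ± 0.25 (adjusted p = 0.999). In camera 5 lists passed at the preset correlation (1 without set A) and 0 with an estimated one. Metallothioneins, the list that passed without each set, shifted upward, with a median of 0.29 (list adjusted p = 2.54e-05) and 0 members passing, also when adjusted over the list alone. Their adjusted p was 0.823 [1.98e-07 to 0.823] with an estimated correlation and 0.346 without the block.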

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

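Single libraries stood apart from the other 3 of their group in 39 of 133 groups of values tested by Dixon's criterion, where chance gives about 1 in 20, or 6.65. Of these, 33 were libraries of set 1, against 3 of set A, 1 of set C and 2 of set D. The rate of 1 in 20 holds for independent, normally distributed values. CPM are skewed, set 1 recurs over groups of the same gene, and some of the 17 genes were named from results of these data. The excess over 6.65 is therefore descriptive. The tests of the spread of paired differences, of the Fc part, of the lymphocyte share and of the fibroblast markers against certolizumab were chosen only after the results they concern were seen.

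IL1B in set 1 was at 12200 CPM in M1 (others 319 to 1400), 12700 with TNF, 14900 with IgG, 8790 with adalimumab, 4710 with etanercept and 4190 with certolizumab, and in M0 the library of set C stood at 316 (others 15.1 to 37.4). IL6 in set 1 was at 105 CPM in M1, 134 with TNF, 129 with IgG and 136 with adalimumab (others at most 17.3). MRC1 in set 1 was at 137 CPM in M1, 846 with adalimumab, 761 with etanercept and 789 with certolizumab (others at most 69.3). MMP1 in set 1 was at 340 CPM in M1, 381 with TNF, 661 with IgG, 2090 with adalimumab and 237 with certolizumab (others at most 82.3). MMP3 in set 1 was at 85.2 CPM in M1, 100 with TNF, 586 with adalimumab and 52.9 with certolizumab (others at most 33.3), and MMP10 at 43.7 in M1. MMP9 in set 1 was at 6610 CPM with TNF, 13700 with adalimumab and 9290 with etanercept (others at most 3890). FCGR2B in set 1 was at 137 CPM in M1, 110 with TNF, 106 with IgG, 154 with adalimumab, 159 with etanercept and 179 with certolizumab (others at most 17.6). In set A, IL10 was at 160 CPM with TNF (others 64.3 to 79), CXCL10 at 37.4 in M0 (others at most 1.56) and the mitochondrial share at 4.85% with IgG (others 8.65% to 8.99%). In set D, total counts were 7.54 M (7541300) in M1 (others 8.62 to 8.81 M) and 11.9 M (11925347) with IgG (others 8.41 to 8.86 M). No explanation of these values was tested.

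Adalimumab differed from both other agents, by the test of the difference itself, in 9 genes, of which 8 are given. Both tests used the same 4 adalimumab libraries, so a gene passing both is not backed by independent results. Of the 12 calls against certolizumab (adjusted p up to 0.05) only 8, 1, 3 and 1 were kept without set 1, A, C and D, and 0 without the block. Against etanercept and certolizumab the log2 fold changes were 1.30 and 1.23 for GREM1, 1.63 and 1.82 for MMP10, 0.96 and 0.71 for IL1R1, -1.32 and -0.93 for CXCL9, -1.18 and -1.13 for RARRES3, -1.94 and -1.55 for OR2I1P, -2.03 and -1.93 for IL31RA and -0.84 and -0.65 for HAPLN3, and OR2I1P overlaps UBD on the other strand. After thinning all libraries to the lowest total, the median size of the 46 called differences was 0.98 against 0.99 before, or 98.7%. Thinning leaves the expected size of a difference nearly unchanged, so this cannot decide whether library depth contributed. Of the named calls, 18 of 21 against etanercept and 7 of 12 against certolizumab were kept after thinning. RNA from fibroblasts stays open for both differences. The sum of 10 markers, scaled to total counts alone, was 16.3 ± 6.31 CPM with adalimumab and 19.1 ± 6.4 with etanercept. It was higher with adalimumab in 1 of 4 sets (difference -2.83 ± 2.13), although FBN1 (3.45 and 3.16) and COL1A2 (3.19 and 2.21) were higher. Levels this low, with THY1 at 0.0658 and 0.205 CPM and DCN at 0.225 and 0.432, cannot decide. Against certolizumab the sum was higher with adalimumab in 3 of 4 sets (13.3 ± 2.98 with certolizumab, difference 2.99 ± 5.15). A difference between the agents themselves also stays open.

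Added TNF changed 1 gene against M1, while each agent changed 1394 or more. A larger spread in the TNF comparison is argued against by the median standard deviation over sets of the paired log2 differences, which was 0.873 times (0.833 to 0.908 without 1 set) that of certolizumab against M1. In the fit, comparisons share the spread of a gene, and the median standard error was 0.19 in both of these. This ratio therefore did not enter the counts. Fc receptors engaged by the agents are argued against as the whole cause, since certolizumab, which has no Fc part, changed 72.8% as many genes against M1 as adalimumab. This share depends on the fit: certolizumab and adalimumab changed 29 and 80 genes without the block, and 659 and 462 with only the libraries compared. A candidate explanation, which stays a hypothesis, is that TNF made by the stimulated cells already acted and was blocked. Of the genes called in both M1 vs M0 and certolizumab vs IgG, which share no library, 87.5% moved in opposite directions. Independent directions would give 49.4%. The explanation predicts this, but any dampening of the response to LPS and IFN-γ would give it too. The IgG group had also received added TNF, so these directions do not separate TNF made by the cells from added TNF.

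Of 20 lymphocyte markers 6, 4 and 3 fell with adalimumab, etanercept and certolizumab against IgG, and none rose. As a list their adjusted p was 0.00322, 0.00892 and 0.000197, and 0.45, 0.441 and 0.357 with an estimated correlation. A smaller share of RNA from T or NK cells is a possible cause. The median over 10 tested T and NK cell markers was -0.73 against IgG, although 1 of 30 tests of single markers passed in edgeR. NCAM1 alone was above 0, at 0.24. All of these markers but CD247 belong to the list, so their fall largely restates that of the list and does not decide the cause. The standard error of the median, 0.13, came from resampling the markers and does not measure the spread between samples. An effect of the agents on the expression of these genes by the macrophages was not tested.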

How the results depend on the processing

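Without the block the counts of genes past the threshold went from 6830 to 4341 in M1 vs M0, 1 to 0 in TNF vs M1, 2233 to 130, 1694 to 86 and 1735 to 84 for adalimumab, etanercept and certolizumab against IgG, 2079 to 80, 1394 to 29 and 1514 to 29 against M1, and 34 to 0 and 12 to 0 for adalimumab against etanercept and certolizumab. Of 754 calls, each of a named gene in 1 comparison, 186 were kept without the block and 567 were lost. FCGR2B in M1 vs M0 went from -1.54 to 0.88. Of the 99 list calls 70 were kept without the block, where 72 lists passed in all.

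Fits of only the libraries compared, which have fewer residual degrees of freedom, gave 3896 genes in M1 vs M0, 4 in TNF vs M1, 5 in IgG vs TNF, 462, 794 and 659 for the agents against M1, and 103, 1 and 6 for adalimumab vs etanercept, adalimumab vs certolizumab and etanercept vs certolizumab. With all 28 libraries in the fit the counts were 0 in TNF vs M1, 1348, 986 and 1057 against IgG, 1113, 732 and 770 against M1, and 4 and 3 for adalimumab against etanercept and certolizumab. Without the filter on low counts they were 203, 31, 391, 243 and 25, and in DESeq2 16, 155, 266, 262 and 170, for TNF vs M1, IgG vs TNF, adalimumab vs etanercept, adalimumab vs certolizumab and etanercept vs certolizumab. In DESeq2 the other counts stayed within 1.5 times. TNF vs M1 gave 0 with the mitochondrial share as a covariate and 0 without the TNF library of set C. These alternatives and the thinning were chosen after seeing the data. The cause was not tested for these shifts.

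Leaving out 1 set at a time gave 5474 to 6282 genes in M1 vs M0, 0 to 5 in TNF vs M1, 0 to 0 in IgG vs TNF, 989 to 2631, 842 to 1792 and 908 to 1683 for the agents against IgG, 777 to 2325, 402 to 1600 and 489 to 1398 against M1, 7 to 51 and 1 to 36 for adalimumab against etanercept and certolizumab, 0 to 0 for etanercept vs certolizumab, and 96 to 110 list calls. Over 3016 refits of a called gene without 1 set, its fold moved by over 1.5 times in 101. With the estimated correlation 30 of 99 list calls passed. With the IgG libraries split between comparisons, and the libraries of each agent reduced with them, the correlation between agents was 0.441, 0.465 and 0.454. With all libraries it was 0.771, 0.788 and 0.809. Of 172 alternative counts 107 stayed within 1.5 times. Of 10431 alternatives for the calls of named genes 9061 kept call and direction, 1369 kept only the direction and 1 turned. Of 693 for called lists 551 kept the call. Results not past the threshold, each of an always-named gene in 1 comparison, numbered 89. Of these, 43 changed sign in some alternative, and 32 of their 1266 alternatives passed.

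Splits of the 8 libraries of a comparison that part all 4 sets number 8, too few for a share under 0.05. The real split and the highest other gave 3896 and 0 genes in M1 vs M0, 4 and 0 in TNF vs M1, 1507 and 0, 1315 and 0, and 1487 and 0 for the agents against IgG, 462 and 0, 794 and 0, and 659 and 0 against M1, and 103 and 0 for adalimumab vs etanercept, so 1 split was as large in each of these. In IgG vs TNF the real split gave 5 and another 29 (3 splits as large), in adalimumab vs certolizumab 1 and 10 (3 splits), and in etanercept vs certolizumab 6 and 12 (2 splits). Of all 35 splits 32 could be fitted, and the highest other of these gave 9 in TNF vs M1 (3 splits as large), 29 in IgG vs TNF (5), 25 in adalimumab vs certolizumab (5), 28 in etanercept vs certolizumab (8), 50 in etanercept vs M1, 2 in certolizumab vs M1, 1 in adalimumab vs etanercept and 0 in the other 5 comparisons. Counts several times the real one point to a structure of the samples or to no difference between the groups, and neither was tested.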

Other observations

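Genes of lipid mediators moved in opposing directions with all 3 agents against IgG. ALOX5, the enzyme that starts leukotriene synthesis, rose by 2.63 ± 0.26, 2.52 ± 0.26 and 2.72 ± 0.26 (highest adjusted p = 1.61e-06) with adalimumab, etanercept and certolizumab. LTA4H, which makes a leukotriene that attracts neutrophils, rose by 0.87 ± 0.16, 0.90 ± 0.16 and 0.94 ± 0.16 (highest adjusted p = 0.000711). PTGS2, the inducible cyclooxygenase, was at -1.30 ± 0.27, -1.22 ± 0.27 and -1.37 ± 0.27 (highest adjusted p = 0.00373) and PTGES, a prostaglandin E synthase, at -1.52 ± 0.26, -1.11 ± 0.26 and -1.37 ± 0.26 (highest adjusted p = 0.0057). Of 14 prostaglandin and lipid mediator genes, 5, 3 and 3 rose and 4, 3 and 3 fell (6, 7 and 6 rose and 5, 3 and 3 fell adjusted over the list alone), with a list adjusted p of 0.611, 0.169 and 0.218. In M1 vs M0 6 rose, 4 fell and 4 did not pass (6 rose and 6 fell adjusted over the list alone), with a median of -0.03, a mean of 0.48 and a list adjusted p of 0.914. Of 17 inflammasome and pyroptosis genes, 4, 4 and 4 rose and 3, 3 and 3 fell (the same adjusted over the list alone), with a list adjusted p of 0.622, 0.369 and 0.332. NAIP was at 2.34 ± 0.26, 2.04 ± 0.27 and 2.37 ± 0.26 (highest adjusted p = 2.2e-05) and NLRC4, its partner, at 0.84 ± 0.15, 0.74 ± 0.15 and 0.80 ± 0.15 (highest adjusted p = 0.0014). In M1 vs M0 11 rose, 4 fell and 2 did not pass (the same adjusted over the list alone), with a list adjusted p of 0.00209, and 0.131 [0.00131 to 0.131] with an estimated correlation.

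Of 23 complement genes tested in M1 vs M0, 11 rose, 5 fell and 7 did not pass (the same adjusted over the list alone), with a list adjusted p of 5.92e-05. Against IgG 6, 7 and 4 rose and 2, 2 and 1 fell (6, 7 and 8 rose and 2, 3 and 3 fell adjusted over the list alone) of 23 with the agents, with a list adjusted p of 0.209, 0.0266 and 0.0685. The etanercept call had an adjusted p of 0.432 [0.0215 to 0.432] with an estimated correlation and 0.0796 without set D and 0.191 without the block. C5AR1, the receptor for a complement-derived anaphylatoxin, rose by 1.42 ± 0.21, 1.26 ± 0.21 and 1.22 ± 0.21 (highest adjusted p = 0.000351). In the TNF ligand and receptor system 3, 2 and 2 rose and 5, 3 and 2 fell (4, 3 and 2 rose and 5, 4 and 2 fell adjusted over the list alone) of 22, with a list adjusted p of 0.979, 0.494 and 0.782. TNFRSF9, a co-stimulatory receptor, was at -0.99 ± 0.13, -0.87 ± 0.13 and -0.85 ± 0.13 (highest adjusted p = 0.000149). Of 11 monocyte and dendritic cell markers, 5, 2 and 2 rose and 2, 2 and 2 fell (8, 4 and 3 rose and 2, 2 and 2 fell adjusted over the list alone), with a list adjusted p of 0.107, 0.203 and 0.384.

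The direction of the changes with the agents was set beside the response to LPS and IFN-γ as a hypothesis that blocking TNF undoes part of that response. Of genes called in both M1 vs M0 and the comparison against IgG, 1283 of 1610 (79.7%) moved in opposite directions with adalimumab, 1109 of 1274 (87%) with etanercept and 1167 of 1333 (87.5%) with certolizumab. Of the genes raised in M1, 623, 564 and 570 fell and 270, 152 and 156 rose further with these agents. Of the genes lowered in M1, 660, 545 and 597 rose and 57, 13 and 10 fell further. Across genes, which are not independent replicates, the correlation of the log2 fold changes with those of M1 vs M0 was -0.377, -0.386 and -0.406. With those of TNF vs M1 it was -0.175, -0.197 and -0.206.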
